A study of Mus musculus with 12 samples.

How the data were processed

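RNA was taken from the gastrocnemius of 12 CD2F1 mice in 4 groups of 3: tumor-free vehicle, tumor-free AR-42, tumor-bearing vehicle and tumor-bearing AR-42. Per the labels' protocols, AR-42 was given by gavage at 50 mg/kg every other day from day 6 after the injection of C-26 cells, the vehicle was 0.5% methylcellulose with 0.1% Tween-80, and hind limb muscle was harvested on day 15. Libraries without strand information were made with the Illumina TruSeq RNA kit, version 2, per the labels' protocols, so that reads of overlapping or antisense genes cannot be told apart. The hour of harvest is not given in the sources used here.

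Alignment was done by the authors with TopHat2 2.0.7 and quantification with Cufflinks, on GRCm38 (mm10), per the submitters' processing notes; the Cufflinks version and the annotation are not given in the sources used here. The authors' table holds FPKM for 34835 loci with 1 column per library, and no scaling between libraries beyond FPKM is stated. Of these loci, 29804 carry a gene symbol, 22970 different ones, and 3750 symbols stand on more than 1 locus. The number of columns of per-sample values not used is 0. For the tumor-free AR-42 group, 2 columns share a header, so these libraries can be assigned to their group but not to a replicate number. They are called unnumbered-a and unnumbered-b. The labels give that header to 1 sample of the group only, and the code of another sample heads no column. That the 2 columns come from different mice is therefore an assumption. FPKM carries no read totals. Values of 3 very short loci move in steps that differ between libraries, but such steps depend on fragment length as well as on depth, so the depth of each library is unknown and no counting interval is given.

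FPKM of loci with the same symbol were summed, and loci without a symbol were left out of the comparisons and tested apart in the same way. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, which gave 11976 genes, 3498 of them on more than 1 locus. Values were taken as log2(FPKM + 1), which understates the change of genes with low values. A linear model with the 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and empirical Bayes moderation with a mean trend, and p-values were two-sided and Benjamini-Hochberg adjusted per comparison, with a call at an adjusted p below 0.05. There were 6 comparisons: the tumor effect under vehicle, the AR-42 effect in tumor-bearing and in tumor-free mice, AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle, the tumor effect under AR-42, and the interaction. The recovery of tumor-changed genes was taken from the calls of the first 2 of these. Nothing shows whether muscles were processed in batches, so p-values measure the spread between these samples. Other software was Python 3.11.15 with matplotlib 3.10.9 for figures.

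Before the data were examined, 37 gene lists, 12 single genes, the comparisons and most alternatives were fixed. Some genes stand on several lists. Lists with at least 5 tested members, 33 in all, were tested with limma's camera with the correlation between genes estimated from the residuals, adjusted over the lists of 1 comparison. Camera with a preset correlation of 0.01 and fry were alternatives. Members called were counted with the adjustment over all genes and adjusted over the list alone. The genes named in the text are the 10 largest increases and 10 largest decreases in log2(FPKM + 1) in each of the first 3 comparisons, and 5 and 5 in the others, among called genes whose 3 libraries of 1 group all lie above the 3 of the other and whose higher group has a mean of at least 5 FPKM, leaving out predicted genes and clone names. For the recovery they are the 10 largest AR-42 effects among genes moved back, for the lists up to 4 called members with the smallest adjusted p, and always the 12 single genes. For the interaction, which holds 4 groups, no such parting of libraries was required. There the highest of the 4 group means had to reach 5 FPKM.

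Genes with a locus listed at exactly 0 in at least 1 library, at 5 FPKM or more in another, and holding at least 10% of the gene's value (519 of the tested genes) were set aside: this definition was chosen after the values were seen. They stay in all counts, and the rule for named genes was extended past them to the next genes, also after the values were seen. Symbols with a comma stand for loci with several genes, and 350 of the tested symbols are of this kind. Single genes and list members were matched to whole symbols, so a member on such a locus, as Cd74 on Cd74,Mir5107, was not counted. Positions are from a GENCODE annotation of GRCm38 by symbol, for 245 of 251 names looked up.

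Overlaps between comparisons that share libraries were set against 100 simulations of unchanged groups and against independent lists of the same sizes. The procedure was tested on simulated data with 200 of 11976 genes changed singly and 30 more shifted together as a list, which left 11746 unchanged. In the tumor effect under vehicle it recovered 79% of genes changed by a log2 of 1 and 97% of those changed by 2, with 10 unchanged genes called. For the AR-42 effect in tumor-bearing mice these figures were 84%, 100% and 6, and for the AR-42 effect in tumor-free mice 80%, 93% and 8. The simulated noise was normal and independent between genes, and fewer genes changed than were called in the real comparisons. These figures therefore need not carry over to the real data. Alternatives were pseudocounts of 0.1 and 0.5, no filter beyond an FPKM above 0 in 1 library, a mean of at least 5 FPKM, quantile and median-ratio scaling, fitting the compared groups alone, a replicate block, robust moderation, library weights, a log2 fold change of at least 1 in addition, loci kept apart, and each library left out in turn. Chosen after seeing the data were fits without genes listed at 0, with the largest locus of each symbol only, without the 2 columns that share a header, and without a block on the same 9 libraries as the block fit.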

Results

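Skeletal muscle wasting in mice carrying the C-26 colon carcinoma, a widely used model of cancer cachexia, was profiled by RNA sequencing of the gastrocnemius, a fast muscle of the calf. CD2F1 mice with a subcutaneous C-26 tumor and tumor-free mice received either AR-42, an oral inhibitor of histone deacetylases, at 50 mg/kg every other day from day 6 after the injection of tumor cells, or its vehicle, and muscle was taken on day 15. There were 12 libraries in 4 groups of 3: tumor-free vehicle, tumor-free AR-42, tumor-bearing vehicle and tumor-bearing AR-42. Expression was given as FPKM, fragments scaled by transcript length and by the total mapped, for 34835 loci. The number of reads behind each library is unknown, since FPKM values carry no totals. Of the genes with a symbol, 11976 reached 1 FPKM in at least 3 libraries and were tested with limma. A value in parentheses after a gene symbol is its log2 fold change on the log2(FPKM + 1) scale, with its standard error after ± where one is given. Levels are mean FPKM ± SD over 3 libraries, and folds are ratios of these means. In counts of genes, at least 2-fold means a change of at least 1 on the log2(FPKM + 1) scale. P-values measure the spread between these samples.

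The tumor-bearing vehicle muscles stood apart from the other 3 groups. On the first principal component, which held 51.1% of the variance, they lay between 61.2 and 86.0, the tumor-bearing AR-42 muscles between -12.9 and -7.56, and the 6 tumor-free muscles between -36.2 and -27.1. The second component, with 12.2% of the variance, placed the tumor-bearing AR-42 muscles between -38.8 and -34.6 and every other library between 0.587 and 22.6. Libraries of 1 group correlated across genes at r between 0.955 and 0.975. Tumor-free and tumor-bearing vehicle libraries correlated at 0.845 to 0.893, and tumor-free vehicle and tumor-bearing AR-42 libraries at 0.934 to 0.943. Genes are not independent replicates.

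The tumor effect under vehicle addresses what the tumor did to the muscle without the drug. The muscle-specific ubiquitin ligases that mark atrophy rose strongly: Trim63 (MuRF1) went from 121 ± 5.77 FPKM in tumor-free vehicle to 2942 ± 772 FPKM in tumor-bearing vehicle muscle, 24.2-fold, and Fbxo32 (atrogin-1) from 47.4 ± 9.26 to 848 ± 139 FPKM, 17.9-fold (n = 3 per group). The metallothioneins Mt1 and Mt2, metal-binding proteins induced by glucocorticoids and cytokines, rose 166-fold, to 8119 ± 2999 FPKM, and 225-fold, to 2698 ± 919 FPKM. Cdkn1a, the cell cycle inhibitor p21, rose 32.8-fold, and Il6ra, the receptor subunit for interleukin 6, rose by 3.78 ± 0.33 on the log2 scale. Among the genes that fell were Casq1, the calcium-binding protein of the sarcoplasmic reticulum, from 2425 ± 124 to 102 ± 48.0 FPKM, and Tmem233, from 321 ± 52.0 to 3.31 ± 1.04 FPKM.

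The limma test called 6810 of the 11976 genes at an adjusted p below 0.05, 3826 higher and 2984 lower; 1417 of the higher and 1092 of the lower ones changed at least 2-fold. The excess of higher genes shrank with quantile scaling (3327 higher and 3199 lower) and was gone with median-ratio scaling (3359 and 3378). Trim63 (4.55 ± 0.27, adjusted p = 7.01e-07) and Fbxo32 (4.14 ± 0.28, adjusted p = 1.5e-06) were above every tumor-free vehicle library in 3 of 3 tumor-bearing vehicle libraries. With Mt2 (7.68 ± 0.37) and Mt1 (7.30 ± 0.32), the largest increases chosen by the fixed rule were Lcn2 (6.20 ± 0.61), a siderophore-binding acute phase protein, Serpina3n (5.48 ± 0.27), an acute phase protease inhibitor, and Cxcl13 (4.90 ± 0.38), a chemokine for B cells. They also held Cdkn1a (4.86 ± 0.28), Fkbp5 (4.73 ± 0.29), a co-chaperone of the glucocorticoid receptor, Trim63, Scgb3a1 (4.48 ± 0.15) and Cnksr1 (4.43 ± 0.27). The largest decreases were Tmem233 (-6.24 ± 0.19), D0H4S114 (-5.93 ± 0.22), annotated as Nrep, Mylk4 (-5.79 ± 0.53), a myosin light chain kinase, Ky (-4.93 ± 0.28), a muscle-specific protease, and Casq1 (-4.68 ± 0.29). Next came Gdap1 (-4.46 ± 0.32), a mitochondrial outer membrane protein, Actc1 (-4.44 ± 0.29), the cardiac alpha-actin, Mybph (-4.33 ± 0.53), Dbp (-4.26 ± 0.48), a transcription factor of the circadian clock, and Plcd4 (-4.23 ± 0.29). Of the genes fixed beforehand, Foxo1 (2.83 ± 0.27), a transcription factor upstream of Trim63 and Fbxo32, Socs3 (8.64-fold), a feedback inhibitor of interleukin 6 signaling, and Myog (1.46 ± 0.20), myogenin, also rose. Mstn, which encodes myostatin, was at 49.2 ± 3.45 and 42.7 ± 14.8 FPKM (adjusted p = 0.443), and Chrna1, a subunit of the acetylcholine receptor, at 7.08 ± 1.31 and 6.24 ± 1.31 FPKM (adjusted p = 0.424), neither past the test. Mt1 and Mt2 are close paralogs, so the share of each is uncertain.

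On GRCm38, with positions from a GENCODE annotation of that build, the protein-coding gene Trim63 lies on chromosome 4 from 134315120 to 134329629 and Fbxo32 on chromosome 15 from 58175879 to 58214932. Mt1 lies on chromosome 8 from 94179082 to 94180327 and Mt2 on chromosome 8 from 94172664 to 94173568. Cdkn1a lies on chromosome 17 from 29090976 to 29100727 and Il6ra on chromosome 3 from 89864059 to 89913196. Casq1 lies on chromosome 1 from 172209894 to 172219868 and Tmem233 on chromosome 5 from 116038755 to 116083244. Values refer to whole loci summed per symbol, so no exon or UTR can be told apart.

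**Figure D1:**
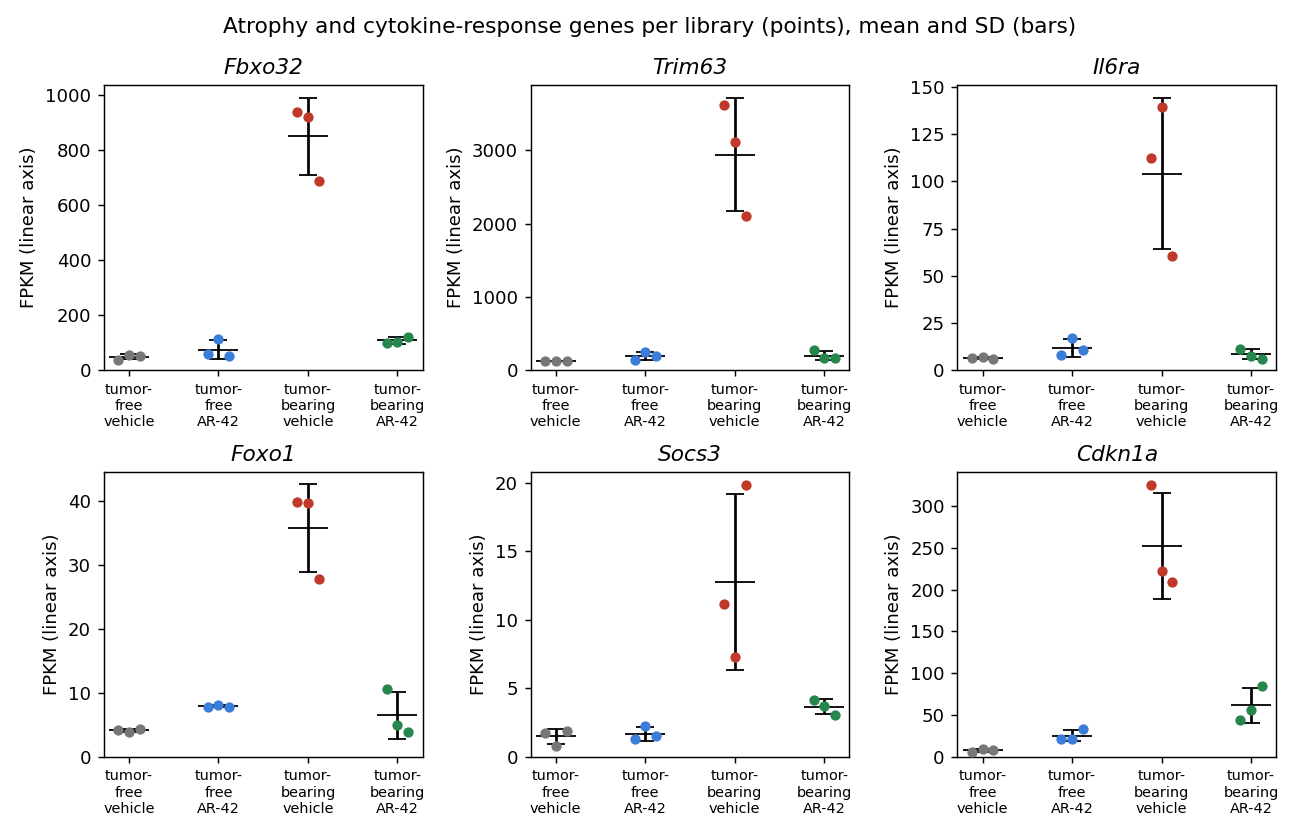
FPKM of 6 genes in each of the 12 libraries (points, linear axes from 0), with horizontal lines at the mean and error bars of 1 SD for each group of 3. Trim63 averages 2942 FPKM in tumor-bearing vehicle muscle and 197 FPKM in tumor-bearing AR-42 muscle.

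Gene lists are given by their members called. Of all tested genes 56.9% were called in this comparison, so a count near that share does not set a list apart. As sets, 0 of 33 lists were called by camera with an estimated correlation between genes, with 3 at an unadjusted p under 0.05, against 13 with its preset correlation of 0.01 and 22 by fry. All 30 tested subunits of the proteasome, the protease that degrades ubiquitin-tagged proteins, were higher (30 and 0 adjusted over the list alone), for example Psmd2 (2.16 ± 0.10), Psmd4 (2.31 ± 0.12), Psmd3 (1.92 ± 0.10) and Psma7 (2.27 ± 0.15). Genes of autophagy and lysosome counted 21 higher and 1 lower of 27 (21 and 1 adjusted over the list alone), with Ctsl (2.67 ± 0.18), the protease cathepsin L, Map1lc3b (1.95 ± 0.14), which coats autophagosomes, and Sqstm1 (2.14 ± 0.18), an autophagy receptor. The FoxO and glucocorticoid response genes counted 17 higher and 4 lower of 27 (18 and 5 adjusted over the list alone). Igfbp5, an IGF-binding protein, fell (-3.53). Interleukin 6 signaling and acute phase genes counted 18 higher and 3 lower of 26 (18 and 3 adjusted over the list alone), with Serpina3n (5.48), Serpina3m (3.06) and Lbp (1.89). Ribosome biogenesis genes counted 19 higher and 1 lower of 20 (19 and 1 adjusted over the list alone), with Rrp12 (1.95), Ddx21 (2.07) and Pes1 (1.40). Heat shock genes counted 13 higher and 0 lower of 17 (13 and 0 adjusted over the list alone), with Hsp90ab1 (1.72) and Hspb1 (2.96). Oxidative stress genes counted 13 higher and 2 lower of 21 (14 and 2 adjusted over the list alone), with Gpx3 (2.08) and Sod1 (1.66). Ubiquitin ligases and related atrophy genes counted 7 higher and 3 lower of 19 (7 and 3 adjusted over the list alone). Besides Trim63 and Fbxo32, Fbxo31 rose (2.85 ± 0.14).

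Mitochondrial and matrix lists held more lower than higher genes, though camera with an estimated correlation called neither (adjusted p = 0.387 and 0.516). Oxidative phosphorylation genes counted 0 higher and 44 lower of 49 (0 and 45 adjusted over the list alone), with Ndufs1 (-1.32 ± 0.13) and Ndufa9 (-1.08 ± 0.11) of complex I, Cycs (-1.37 ± 0.14), cytochrome c, and Cox7a1 (-2.03 ± 0.22) of complex IV. Extracellular matrix genes counted 7 higher and 20 lower of 33 (8 and 20 adjusted over the list alone), with the collagen genes Col1a1 (-3.76), Col1a2 (-3.14) and Col6a1 (-1.91) and Fmod (-2.72 ± 0.20), a collagen-binding proteoglycan. All 7 tested tendon and cartilage markers fell with them (0 and 7 adjusted over the list alone), among them Kera (-3.47 ± 0.11), Tnmd (-3.44 ± 0.15) and Chad (-2.77 ± 0.22). The tendon content of the muscle pieces is not given, so it cannot be told apart from a matrix change in the muscle. The same holds for both AR-42 effects and the interaction, where these lists also moved together. Interferon response and antigen presentation genes counted 0 higher and 12 lower of 19 (0 and 12 adjusted over the list alone), with Iigp1 (-3.12), Gbp3 (-1.36) and Psmb9 (-1.15). Without tumor-free vehicle replicate 2 or tumor-bearing vehicle replicate 2, 7 were lower. Slow fibre contractile genes counted 3 higher and 10 lower of 17 (3 and 10 adjusted over the list alone), with myoglobin, Mb (-2.21 ± 0.29), and 6 lower without tumor-free vehicle replicate 3.

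The fry test asks whether a list moves on balance one way and compares it with no other genes. With an estimated correlation the camera adjusted p was 0.303 for the proteasome, 0.253 for autophagy and 0.327 for the FoxO list. It was 0.253 for the interleukin 6 list and 0.253 for ribosome biogenesis. It was 0.414 for heat shock, 0.253 for oxidative stress, 0.387 for oxidative phosphorylation, 0.516 for the matrix, 0.253 for tendon, 0.327 for interferon, 0.721 for slow fibre and 0.681 for the ubiquitin ligases. With the preset correlation the camera adjusted p was 1.16e-11 for the proteasome and 1.54e-11 for oxidative phosphorylation.

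The counts of the other lists follow. Cytokine and NF-kB genes counted 9 higher and 2 lower of 16 (10 and 2 adjusted over the list alone), with Tnfrsf12a (3.39 ± 0.29), the receptor of TWEAK. ATF4 and amino acid stress genes counted 11 higher and 4 lower of 19 (11 and 4 adjusted over the list alone) and genes often raised by inhibitors of histone deacetylases 9 higher and 3 lower of 17 (10 and 3 adjusted over the list alone). Glycolysis and glycogen genes counted 10 higher and 16 lower of 29 (10 and 16 adjusted over the list alone). Fatty acid oxidation and lipid handling genes counted 12 higher and 8 lower of 30 (12 and 8 adjusted over the list alone), with Pnpla2 (2.58 ± 0.17), the triglyceride lipase ATGL. Branched-chain amino acid breakdown genes counted 8 higher and 5 lower of 18 (8 and 5 adjusted over the list alone). The glycolysis list had a median log2 fold change of -0.80 while fry leaned upward. The circadian clock list, with 6 higher and 4 lower of 17 (6 and 4 adjusted over the list alone), and the satellite cell list, with 4 higher and 5 lower of 15 (4 and 5 adjusted over the list alone), also differed in sign between median and test. Denervation and neuromuscular junction genes counted 8 higher and 6 lower of 21 (8 and 6 adjusted over the list alone). Genes of myostatin, activin and BMP signaling counted 6 higher and 7 lower of 25 (6 and 7 adjusted over the list alone). Histone deacetylases counted 4 higher and 5 lower of 17 (4 and 5 adjusted over the list alone) and cell cycle genes 1 higher and 3 lower of 6 (1 and 3 adjusted over the list alone). Fast fibre genes counted 7 higher and 4 lower of 14 (7 and 4 adjusted over the list alone), but 7 of the 14 are listed at 0 in some libraries. Macrophage markers counted 5 higher and 0 lower of 13 (5 and 0 adjusted over the list alone), with Cd68 at 3.63 ± 0.34 and 8 higher without tumor-free vehicle replicate 1. Cd68 does not stand for its list. From tumor-free to tumor-bearing vehicle muscle C1qa went from 8.84 to 13.3 FPKM and Csf1r from 4.24 to 4.00 FPKM. Endothelial markers counted 7 higher and 1 lower of 12 (7 and 1 adjusted over the list alone). Neutrophil markers counted 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone) and adipocyte markers 0 higher and 2 lower of 13 (0 and 2 adjusted over the list alone). Fibroblast markers counted 3 higher and 5 lower of 10 (3 and 5 adjusted over the list alone), smooth muscle markers 1 higher and 5 lower of 9 (1 and 5 adjusted over the list alone) and Schwann cell markers 0 higher and 2 lower of 6 (0 and 0 adjusted over the list alone). Of 4 red blood cell markers 0 were called (0 adjusted over the list alone), and of 4 sex-linked genes 2 were higher (2 adjusted over the list alone). Both lists were too short for limma's list tests. No lymphocyte or epithelial marker found under its own symbol reached the filter, with highest values of 1.38 and 0.536 FPKM. The former is Cd79a in tumor-bearing AR-42 replicate 1, against 0.125 and 0.113 FPKM in replicates 2 and 3. Every lymphocyte marker found had its highest value in that library.

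**Figure D2:**
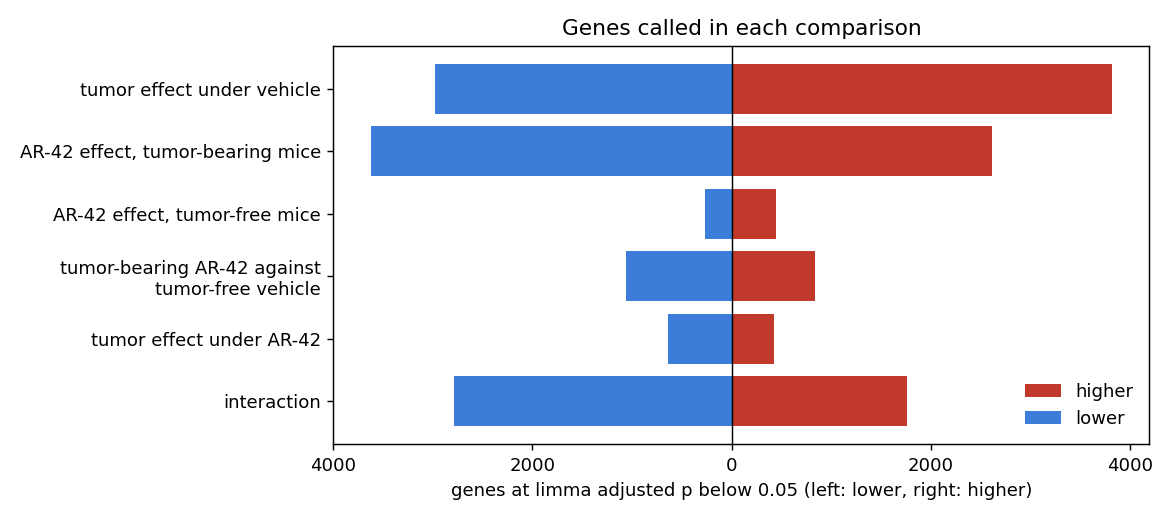
Number of genes at a limma adjusted p below 0.05 in each comparison, higher to the right and lower to the left. The tumor effect under vehicle has 3826 higher and 2984 lower genes, the tumor effect under AR-42 424 and 637.

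Some of the most abundant muscle genes are listed at exactly 0 FPKM in whole groups, and no fold is given for them. Acta1 (skeletal actin), Ckm (creatine kinase), Tnnt3 (fast troponin T) and Atp2a1 (the calcium pump SERCA1) are listed at 0 in all 12 libraries. Tpm1 (tropomyosin) is listed at 0 in 9 libraries and at 5319, 4445 and 5698 FPKM in tumor-bearing vehicle muscle. Gapdh, Myl1 and Mylpf, the last 2 being myosin light chains, are listed at 0 in the 6 tumor-free libraries. Gapdh is listed at 2748, 2100.4 and 2186 FPKM in tumor-bearing vehicle and 2459.6, 2432 and 2405 FPKM in tumor-bearing AR-42 muscle, Myl1 at 5096, 3794 and 4122 and at 10455, 10026 and 11180.1, and Mylpf at 4432, 3086 and 4859 and at 8059.5, 8389 and 9303. The main loci of Pvalb and Tnnc2 are likewise listed at 0 in tumor-free muscle and that of Tnni2 in all but tumor-bearing AR-42 muscle, where Tnni2 summed to 8537, 11615 and 11784 FPKM. Actn3 and Pygm are listed at 0 in the 3 tumor-free AR-42 libraries alone, Neb and Ubc above 0 in the 3 tumor-free vehicle libraries alone, where Neb had 377, 796 and 972 FPKM. The main locus of Pdk4, an inhibitor of pyruvate oxidation, is listed at 0 in tumor-bearing vehicle and at 96.4, 216 and 205 FPKM in tumor-free vehicle muscle. Counts of called genes include such genes. Without the 519 of them, the tumor effect under vehicle counted 3699 higher and 2877 lower. No locus carried Myh4, the fast myosin fixed for description, as its only symbol, and loci with several symbols were not searched for it. The summed value of Hdac4 with the tumor rests in part on a locus listed at 0 in the tumor-free groups. Its other 2 loci moved in opposite directions between tumor-free and tumor-bearing vehicle muscle, 1 from 4.97, 5.61 and 5.98 to 8.49, 7.56 and 8.10 FPKM (0.47, limma adjusted p = 0.0375) and 1 from 2.78, 3.88 and 3.31 to 0.953, 0.628 and 1.13 FPKM, so no direction is given for the gene.

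The fixed rule for named genes also took other genes with a locus listed at 0 in at least 1 library: Olfr1033, Snord69, Olfr56, Snord91a, Mir3112, Gbp10, Adamts2, Usp13, Ralgapa1, Pycr1, Prodh, N4bp2l1, Rif1 and Mmrn2. Olfr1033 summed to 128469, 107215 and 113562 FPKM in tumor-bearing vehicle muscle, 7395, 8016 and 9686 FPKM in tumor-bearing AR-42 muscle, 3279, 4401 and 4787 FPKM in tumor-free AR-42 muscle and 0.297, 0.396 and 2478 FPKM in tumor-free vehicle muscle.

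**Figure D3:**
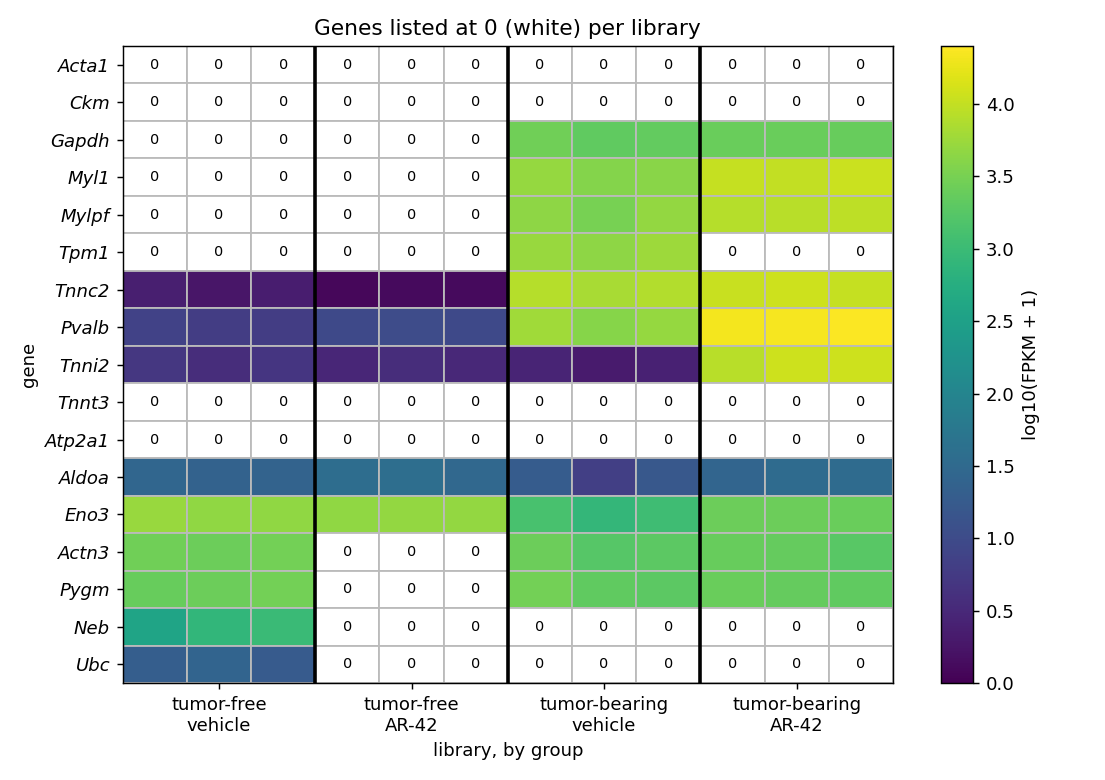
Color shows log10(FPKM + 1) of 17 muscle and housekeeping genes (vertical axis) in each of the 12 libraries (horizontal axis, by group), with white cells listed at 0. Acta1 and Ckm are listed at 0 in all 12 libraries, Gapdh in the 6 tumor-free ones.

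The AR-42 effect in tumor-bearing mice addresses what the drug changed in the wasting muscle. The atrophy ligases fell back: Trim63 was 14.9-fold lower, at 197 ± 61.4 FPKM under AR-42 against 2942 ± 772 under vehicle, and Fbxo32 7.91-fold lower, at 107 ± 12.4 against 848 ± 139 FPKM (n = 3 per group). Mt1 and Mt2 fell from 8119 and 2698 FPKM to 216 ± 66.5 and 99.7 ± 34.2 FPKM. Il6ra fell by 3.45 ± 0.33 on the log2 scale and Foxo1 by 2.39 ± 0.27. Casq1 rose from 102 ± 48.0 to 1053 ± 88.6 FPKM and Tmem233 from 3.31 ± 1.04 to 165 ± 22.3 FPKM.

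The limma test called 6240 genes, 2615 higher and 3625 lower, with 813 higher and 1218 lower by at least 2-fold. With median-ratio scaling the majority turned, to 3220 higher and 3033 lower, so the larger number of lower genes depends on the scaling. The largest increases under the fixed rule were Tmem233 (5.29), Mybph (4.36), Mylk4 (4.20), D0H4S114 (3.99), Lrrc38 (3.86), Actc1 (3.73), Ky (3.73), Aqp4 (3.68), Iigp1 (3.55) and Casq1 (3.47). Mybph is a myosin-binding protein, Lrrc38 a subunit of potassium channels, Aqp4 the water channel of fast fibres and Iigp1 an interferon-induced GTPase. The largest decreases were Ctxn3 (-8.08 ± 2.13), Mt1 (-5.21), Mt2 (-4.74), Lcn2 (-4.67), Cnksr1 (-4.02) and Ifi30 (-3.90), with Ifi30 a lysosomal thiol reductase, then Trim63 (-3.90 ± 0.27), at adjusted p = 4.14e-06, Mustn1 (-3.86 ± 0.23), a small nuclear protein of muscle, Ryr3 (-3.69 ± 0.87), a calcium release channel, and Doc2b (-3.55 ± 0.34). Among the genes fixed beforehand, Fbxo32 (-2.96 ± 0.28), Cdkn1a (-2.05 ± 0.28) and Socs3 (-1.47 ± 0.30) fell. Myog (-0.65 ± 0.20) fell too, but settings that ended that call included quantile scaling (-0.50) and leaving out tumor-bearing vehicle replicate 3 (-0.57) or tumor-bearing AR-42 replicate 1 (-0.55).

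Several lists with more higher than lower genes in the tumor effect had more lower than higher ones with AR-42. Of all genes that rose with the tumor, 77.9% were called lower with AR-42, and of all tested genes 52.1% were called. Both comparisons share the tumor-bearing vehicle libraries with opposite sign, so a reversal alone does not set a list apart. As sets, 0 of 33 were called by camera with an estimated correlation, with 1 at an unadjusted p under 0.05, against 14 with the preset correlation and 21 by fry. All 30 tested proteasome subunits were lower (0 and 30 adjusted over the list alone), among them Psmd2 (-1.95 ± 0.10), Psmd4 (-2.28 ± 0.12) and Psma7 (-2.51 ± 0.15). Autophagy and lysosome genes counted 1 higher and 19 lower of 27 (1 and 21 adjusted over the list alone), with Bnip3l (-1.40), Ctsd (-1.43), Sqstm1 (-1.94) and Ctsl (-1.92). Ribosome biogenesis genes counted 0 higher and 19 lower of 20 (0 and 19 adjusted over the list alone), with Pes1 (-1.60) and Ddx21 (-1.87). FoxO and glucocorticoid response genes counted 4 higher and 19 lower of 27 (4 and 19 adjusted over the list alone), with Eif4ebp1 (-3.28 ± 0.24), a repressor of translation, lower and Igfbp5 (3.21 ± 0.17) higher. Interleukin 6 and acute phase genes counted 1 higher and 13 lower of 26 (1 and 13 adjusted over the list alone), with Serpina3n (-2.87) and Serpina3m (-2.26). Oxidative stress genes counted 2 higher and 11 lower of 21 (2 and 14 adjusted over the list alone), heat shock genes 1 higher and 6 lower of 17 (1 and 6 adjusted over the list alone), and ubiquitin ligases and related atrophy genes 3 higher and 7 lower of 19 (3 and 8 adjusted over the list alone). Genes often raised by inhibitors of histone deacetylases counted 3 higher and 9 lower of 17 (3 and 9 adjusted over the list alone). The lower ones included Mt1, Mt2 and Cdkn1a, which had risen with the tumor.

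Matrix genes counted 18 higher and 4 lower of 33 (19 and 4 adjusted over the list alone), at a camera adjusted p of 0.411 with an estimated correlation, with Col3a1 (2.30), Fmod (1.97), Col6a3 (1.69) and Col6a1 (1.47). Tendon and cartilage markers counted 6 higher and 0 lower of 7 (7 and 0 adjusted over the list alone), with Kera (2.37) and Tnmd (1.68). Adipocyte markers counted 7 higher and 0 lower of 13 (7 and 0 adjusted over the list alone), with Plin1 (2.59 ± 0.45), the coat protein of lipid droplets, Fasn (1.65 ± 0.39) and Cfd (1.97 ± 0.51). Smooth muscle and pericyte markers counted 5 higher and 0 lower of 9 (5 and 0 adjusted over the list alone). Interferon genes counted 5 higher and 0 lower of 19 (5 and 0 adjusted over the list alone), and 10 higher with median-ratio scaling. Oxidative phosphorylation genes counted 19 higher and 1 lower of 49 (18 and 1 adjusted over the list alone), with Ndufs1 (0.99) and Cox7a1 (1.35). That count was 39 higher with quantile scaling, 29 with median-ratio scaling and 11 without tumor-bearing vehicle replicate 2. Glycolysis and glycogen genes counted 15 higher and 6 lower of 29 (15 and 6 adjusted over the list alone), with Pgm2 (2.16 ± 0.14), a phosphoglucomutase, and Gpd1 (2.60 ± 0.26), a glycerol phosphate dehydrogenase. Fast fibre genes had a positive median while fry leaned downward, and 7 of them are listed at 0 in some libraries.

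With an estimated correlation the camera adjusted p was 0.411 for the proteasome, autophagy, ribosome biogenesis, the FoxO list, the matrix, tendon, interferon, smooth muscle and the genes often raised by these inhibitors, 0.464 for interleukin 6, 0.569 for glycolysis, 0.411 for oxidative stress, and 0.589 for oxidative phosphorylation, adipocytes, heat shock and the ubiquitin ligases. Median-ratio scaling moved the median log2 fold change of all genes by 0.11, from -0.06 to 0.05.

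The recovery of tumor-changed genes asks how much of the tumor effect the drug moved back. Of the 6810 genes called with the tumor, 4938 (72.5%) were called in the opposite direction under AR-42: 2979 of 3826 that had risen and 1959 of 2984 that had fallen. AR-42 moved 25 genes further, and 1326 (19.5%) were called between tumor-bearing AR-42 and tumor-free vehicle muscle. Of these, 477 were higher and 690 lower in both comparisons, while 94 that had risen with the tumor now lay below the tumor-free level and 65 that had fallen lay above it. Over the called genes, the median share of the tumor effect left under AR-42 was 18.9%, with 15.9%, 20.0% and 20.4% in the 3 tumor-bearing AR-42 libraries (SD 2.53) and an interquartile range from -6.07% to 47.4%. This share is measured from tumor-free vehicle muscle, so it also holds changes that the drug makes without a tumor. The genes with the largest movement back included Tmem233 (5.29 ± 0.19), Mt1 (-5.21 ± 0.32), Mt2 (-4.74 ± 0.37), Lcn2 (-4.67 ± 0.61), Mybph (4.36 ± 0.53), Mylk4 (4.20 ± 0.53), Cnksr1 (-4.02 ± 0.27), D0H4S114 (3.99 ± 0.22), Ifi30 (-3.90 ± 0.21) and Trim63 (-3.90 ± 0.27). Trim63 ended at 197 FPKM against 121 in tumor-free vehicle muscle, while Tmem233 ended at 165 against 321 and D0H4S114 at 31.6 against 123. The gap between the shares of risen and fallen genes moved back shrank with other scalings. With median-ratio scaling 2478 of 3359 risen and 2382 of 3378 fallen genes moved back, and with quantile scaling 2483 of 3327 and 2164 of 3199.

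The comparisons share the tumor-bearing vehicle libraries with opposite sign, so some reversal arises by chance. Their log2 fold changes correlated across genes at r = -0.82, against -0.502 in 100 simulations of unchanged groups, with a covariance of -0.718 against a simulated -0.0392. Independent lists of these sizes would share 1158 genes up then down and 652 down then up, against the 2979 and 1959 seen. Part of the excess may come from the shared libraries. Without any shared library, the tumor effect under AR-42 had a slope of 0.194 on the tumor effect under vehicle over the 6810 genes, or 0.145 without genes listed at 0, with r = 0.444 across these genes and the same sign in 61.4% of them.

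**Figure D4:**
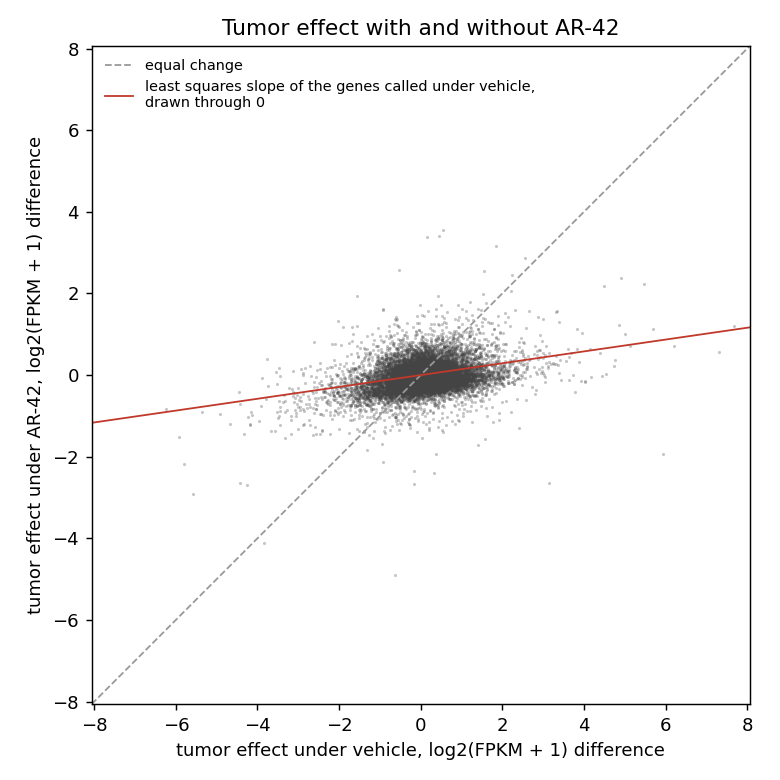
Each point is a tested gene not listed at 0, with its difference in log2(FPKM + 1) with tumor under vehicle (horizontal axis) and under AR-42 (vertical axis), which share no library; the dashed line marks equal change. The solid line, drawn through 0, has the slope of 0.145 of the genes called under vehicle.

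Across tumor-free vehicle, tumor-free AR-42, tumor-bearing vehicle and tumor-bearing AR-42 muscle, in that order, Il6ra stood at 6.24 ± 0.399, 11.7 ± 4.82, 104 ± 40.1 and 8.30 ± 2.70 FPKM, and Foxo1 at 4.13 ± 0.275, 7.88 ± 0.149, 35.8 ± 6.84 and 6.47 ± 3.63 FPKM. Socs3 stood at 1.48 ± 0.583, 1.68 ± 0.507, 12.8 ± 6.45 and 3.65 ± 0.562 FPKM, and Myog at 5.18 ± 1.90, 5.36 ± 0.842, 15.5 ± 1.88 and 9.55 ± 1.35 FPKM. Mstn stood at 49.2 ± 3.45, 43.9 ± 13.2, 42.7 ± 14.8 and 44.4 ± 9.15 FPKM and Chrna1 at means of 7.08, 6.04, 6.24 and 4.74 FPKM (n = 3 per group). Mstn and Chrna1 passed limma's test in 0 of the 6 comparisons, with smallest adjusted p = 0.443 and 0.0706.

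The AR-42 effect in tumor-free mice addresses what the drug does to muscle without a tumor. Fkbp5, the glucocorticoid-induced co-chaperone, rose 6.49-fold, from 7.07 ± 1.94 to 45.9 ± 21.6 FPKM, Actc1 3.87-fold, from 163 ± 37.0 to 629.9 ± 176 FPKM, and Cdkn1a from 7.70 ± 2.00 to 25.0 ± 6.76 FPKM (n = 3 per group). The collagen genes Col1a1 and Col1a2 fell 5.46-fold and 3.26-fold, to 8.57 ± 2.04 and 19.6 ± 2.20 FPKM. Hemoglobin transcripts fell as well, Beta-s from 244 ± 170.4 to 41.7 ± 23.7 FPKM. The atrophy ligases did not pass the test: Trim63 was at 121 ± 5.77 and 193 ± 56.6 FPKM (adjusted p = 0.209) and Fbxo32 at 47.4 ± 9.26 and 72.9 ± 34.3 FPKM (adjusted p = 0.286).

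The limma test called 711 genes, 444 higher and 267 lower, with 83 higher and 62 lower by at least 2-fold. The largest increases under the fixed rule were Bc1,Fgf22 (2.75 ± 0.38), a locus that holds a brain cytoplasmic RNA and a growth factor gene, Fkbp5 (2.46 ± 0.29), at adjusted p = 0.00177, and Nfil3 (1.95 ± 0.28), a clock-linked repressor. Next came Actc1 (1.94 ± 0.29), Glul (1.93 ± 0.31), glutamine synthetase, Tph1 (1.92), Lrp11 (1.87), Plb1 (1.85), Camk2n2 (1.84) and Mt2 (1.74 ± 0.37). The largest decreases were the locus 2210403K04Rik,Mir22,Tlcd2 (-2.72 ± 0.60), Beta-s (-2.43 ± 0.48), a beta-globin annotated as Hbb-bs, Col1a1 (-2.32 ± 0.27), Hba-a2 (-2.21), H2-Q8 (-1.82), Hbb-b1 (-1.78), Tnmd (-1.73), Col1a2 (-1.65), Cd74,Mir5107 (-1.59 ± 0.38) and Emid1 (-1.53 ± 0.37). Cdkn1a was called at adjusted p = 0.0111. Globin and H2-Q8 reads can be shared with near-identical copies, and at loci with several symbols the gene that changed cannot be told.

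Extracellular matrix genes counted 1 higher and 9 lower of 33 (1 and 10 adjusted over the list alone), with Col1a1 (-2.32), Col1a2 (-1.65), Postn (-1.27) and Sparc (-0.68). Tendon and cartilage markers counted 0 higher and 5 lower of 7 (0 and 6 adjusted over the list alone), with Tnmd (-1.73), Kera (-1.28) and Cilp2 (-1.12). As the tendon content of the pieces is not given, it cannot be told apart from a change of collagen genes in the muscle. FoxO and glucocorticoid response genes counted 6 higher and 0 lower of 27 (8 and 0 adjusted over the list alone), with Fkbp5 (2.46), Mt2 (1.74), Cdkn1a (1.58) and Mt1 (1.51). Of these, Mt2, Cdkn1a and Mt1 also stand on the list of genes often raised by inhibitors of histone deacetylases. Their rise therefore cannot be credited to either list. Endothelial markers counted 1 higher and 0 lower of 12 (7 and 0 adjusted over the list alone), with Eng (0.59 ± 0.14). Red blood cell markers counted 0 higher and 3 lower of 4 (0 and 3 adjusted over the list alone). Proteasome subunits counted 3 higher and 0 lower of 30 (3 and 0 adjusted over the list alone). The camera test with an estimated correlation called 0 of 33 lists, 1 at an unadjusted p under 0.05, against 8 with the preset correlation and 10 by fry. Camera at the estimated correlation gave an adjusted p of 0.552 for the matrix, tendon, the FoxO list and endothelial markers. Leaving out single libraries left between 3 and 5 lower matrix genes (3 without tumor-free vehicle replicate 2 or tumor-free AR-42 replicate unnumbered-a), 2 to 4 lower tendon markers and 2 to 6 higher FoxO genes.

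This comparison rests on few libraries. The count fell to 471, 269 and 304 genes without tumor-free vehicle replicate 1, 2 or 3, to 364 without tumor-free AR-42 replicate 1, to 211 and 358 without either unnumbered tumor-free AR-42 library. It fell to 33 without both of these, whose columns share a header, and to 424 of 8238 genes with a mean FPKM of at least 5, but rose to 2603 with library weights. Without both unnumbered libraries, Fkbp5, Tph1, Lrp11 and Tnmd kept their calls, and the others named among the largest changes, and Cdkn1a, lost theirs. Among the lost ones some changes were no smaller, as for Bc1,Fgf22 (2.94) and H2-Q8 (-2.27). Others shrank, as for Hba-a2 (-1.06) and Mt2 (0.95). Without unnumbered-a alone, calls were lost for Beta-s (-2.35), Hba-a2 (-2.08), Hbb-b1 (-1.76), H2-Q8 (-1.80), Emid1 (-1.29), Mt2 (1.47) and the 2210403K04Rik,Mir22,Tlcd2 (-2.48) and Cd74,Mir5107 (-1.60) loci. All 8 were lost without unnumbered-b too, and all but Beta-s without at least 1 tumor-free vehicle library.

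The comparison of AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle shows what differed from healthy muscle after treatment. Cdkn1a was higher, at 61.4 ± 21.1 FPKM against 7.70 ± 2.00 (n = 3 per group), and Mt2, at 99.7 ± 34.2 FPKM, was 8.33-fold higher. The difference holds the effect of the drug as well as that of the tumor. Both genes were also called higher with AR-42 in tumor-free mice, where Mt2 was at 44.3 ± 18.7 FPKM. Arntl, which encodes the core clock activator BMAL1, was at 23.3 ± 7.32 against 1.93 ± 0.308 FPKM, and Dbp, a clock output gene, at 6.13 ± 5.61 against 64.0 ± 5.85 FPKM. Trim63, at 197 ± 61.4 against 121 ± 5.77 FPKM, did not pass the test (adjusted p = 0.126), whereas Fbxo32 was higher (1.17 ± 0.28, adjusted p = 0.0183).

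The limma test called 1906 genes, 842 higher and 1064 lower. Which direction held more genes depended on the setting: 953 were higher and 945 lower with median-ratio scaling, 1086 and 1080 with no filter beyond an FPKM above 0 in 1 library, and 189 and 137 with a change of at least 2-fold. The largest increases under the fixed rule were Dnm3os (3.41), Cxcl13 (3.03), Scgb3a1 (3.03), Arntl (3.01) and Mt2 (2.94), and the largest decreases Dbp (-3.47), 2210403K04Rik,Mir22,Tlcd2 (-2.90), Emid1 (-2.41), Bhlhe41 (-2.02) and D0H4S114 (-1.94). Bhlhe41 is a clock repressor. Dnm3os is an antisense gene on chromosome 1 from 162217623 to 162225550, and with libraries without strand its reads cannot be told from those of the gene it overlaps. Interleukin 6 and acute phase genes counted 11 higher and 0 lower of 26 (12 and 1 adjusted over the list alone). NF-kB and cytokine genes counted 5 higher and 0 lower of 16 (8 and 0 adjusted over the list alone). Macrophage markers counted 6 higher and 0 lower of 13 (8 and 0 adjusted over the list alone) and endothelial markers 7 higher and 0 lower of 12 (8 and 0 adjusted over the list alone). Tendon markers counted 0 higher and 5 lower of 7 (0 and 6 adjusted over the list alone). Clock genes counted 3 higher and 7 lower of 17 (3 and 9 adjusted over the list alone), with 4 lower without tumor-free vehicle replicate 3. Proteasome subunits counted 1 higher and 2 lower of 30 (0 and 0 adjusted over the list alone). Oxidative phosphorylation genes counted 0 higher and 15 lower of 49 (0 and 37 adjusted over the list alone), with 4 lower under quantile scaling and 0 without tumor-bearing AR-42 replicate 2. Camera with an estimated correlation called 0 of 33 lists, 4 at an unadjusted p under 0.05, against 8 with the preset correlation and 12 by fry. Camera at the estimated correlation gave an adjusted p of 0.347 for interleukin 6 and endothelial markers, 0.208 for NF-kB, 0.449 for macrophages and the clock, 0.386 for tendon and 0.53 for oxidative phosphorylation.

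The number of genes called fell to 1176 and 1086 without tumor-free vehicle replicate 1 or 2 and to 1266 and 907 without tumor-bearing AR-42 replicate 1 or 2. It fell to 1260 with these 2 groups fitted alone and to 1244 of 8238 genes with a mean FPKM of at least 5, and rose to 4722 with library weights. The call for Fbxo32 was lost without tumor-free vehicle replicate 1 (1.01), tumor-bearing AR-42 replicate 2 (1.20) or replicate 3 (1.08). Myog (0.81 ± 0.20) lost its call in settings that included the 2 groups fitted alone and fits without either of 2 tumor-free vehicle or 2 tumor-bearing AR-42 libraries (0.72, 0.65, 0.72 and 0.79).

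The tumor effect under AR-42 compares tumor-bearing with tumor-free mice that all received the drug. Hemoglobin transcripts stood out: Beta-s was at 464 ± 113 FPKM in tumor-bearing and 41.7 ± 23.7 FPKM in tumor-free muscle, and Hba-a2 at 67.9 ± 20.3 against 6.53 ± 5.65 FPKM (n = 3 per group). Hp, the hemoglobin-binding acute phase protein haptoglobin, was higher (2.87 ± 0.46). Actc1 was lower, at 98.3 ± 12.7 against 629.9 ± 176 FPKM, as was Dbp, at 6.13 ± 5.61 against 39.0 ± 15.5 FPKM. The ligases Trim63 (0.03 ± 0.27, adjusted p = 0.953) and Fbxo32 (0.64 ± 0.28, adjusted p = 0.159) did not pass the test.

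The limma test called 1061 genes, 424 higher and 637 lower. The excess of lower genes shrank with median-ratio scaling (480 higher and 485 lower) and quantile scaling (332 and 355), and it turned with a change of at least 2-fold (104 and 79). It also turned without tumor-free AR-42 replicate unnumbered-a (189 and 179), unnumbered-b (162 and 157) or both (38 and 29), and without tumor-bearing AR-42 replicate 2 (93 and 67) or replicate 3 (286 and 277). The largest increases under the fixed rule were Beta-s (3.56), Hba-a2 (3.41), Hbb-b1 (3.38), Hp (2.87) and Bicd2 (2.55) and the largest decreases Dbp (-2.69), Pcsk5 (-2.66), Actc1 (-2.64), Mylk4 (-2.18) and Angel1 (-2.13). Pcsk5 is a proprotein convertase and Bicd2 a dynein adaptor. Cdkn1a (1.24 ± 0.28, adjusted p = 0.0267) and Myog (0.73 ± 0.20, adjusted p = 0.0469) were higher. NF-kB and cytokine genes counted 5 higher and 0 lower of 16 (7 and 0 adjusted over the list alone). Interleukin 6 and acute phase genes counted 11 higher and 0 lower of 26 (12 and 1 adjusted over the list alone). Matrix genes counted 12 higher and 0 lower of 33 (18 and 1 adjusted over the list alone) and macrophage markers 3 higher and 0 lower of 13 (10 and 0 adjusted over the list alone). Red blood cell markers counted 4 higher and 0 lower of 4 (4 and 0 adjusted over the list alone). Oxidative phosphorylation genes counted 0 higher and 8 lower of 49 (0 and 30 adjusted over the list alone), with 0 under quantile scaling and between 0 and 3 without single libraries. Camera with an estimated correlation called 0 of 33 lists, 4 at an unadjusted p under 0.05, against 14 with the preset correlation and 10 by fry. Camera at the estimated correlation gave an adjusted p of 0.0686 for NF-kB, 0.202 for interleukin 6, 0.337 for the matrix, 0.561 for macrophages and 0.583 for oxidative phosphorylation. Without tumor-bearing AR-42 replicate 2, 3 higher matrix genes and 5 higher interleukin 6 genes were left.

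The number of genes called fell to 250, 368 and 319 without tumor-free AR-42 replicate 1, unnumbered-a or unnumbered-b and to 160 and 563 without tumor-bearing AR-42 replicate 2 or 3. It fell to 67 without both libraries whose columns share a header, to 687 under quantile scaling and to 577 with the 2 groups fitted alone, and rose to 3296 with library weights. Without both libraries that share a header, Actc1 alone of the genes named here kept its call. The changes of Dbp (-3.23), Hp (3.41) and Bicd2 (2.76) were then larger than with all libraries. Those of Beta-s (2.72), Hba-a2 (2.26) and Pcsk5 (-2.03) were smaller. Without tumor-bearing AR-42 replicate 2, calls were lost for Mylk4 (-2.03), Angel1 (-2.26), Bicd2 (2.32), Cdkn1a (1.28), Dbp (-2.52), Pcsk5 (-2.37) and Myog (0.65), and those for Mylk4, Angel1, Bicd2, Cdkn1a, Dbp and Myog also without tumor-free AR-42 replicate 1. The Myog and Bicd2 calls ended in each of the 6 fits with a library of these groups left out and in other settings. These included a pseudocount of 0.1 and quantile scaling for Myog and robust moderation for Bicd2.

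The interaction of tumor and AR-42 tests whether the AR-42 effect differed with and without a tumor. It is equally a test of whether the tumor effect differed with and without the drug. AR-42 lowered Trim63 in tumor-bearing mice (-3.90 ± 0.27), while in tumor-free mice the value was 0.62 ± 0.27, an interaction of -4.52 ± 0.38 (adjusted p = 3.89e-05). Mt1 and Mt2 fell with the drug in tumor-bearing mice and rose in tumor-free mice, from 48.8 ± 6.74 to 147 ± 49.1 FPKM for Mt1 (n = 3 per group). Col1a1 went the other way, with 46.8 ± 9.97 FPKM in tumor-free vehicle and 8.57 ± 2.04 in tumor-free AR-42 muscle, against 2.54 ± 0.903 and 11.8 ± 3.60 in tumor-bearing vehicle and AR-42 muscle.

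The limma test of the interaction called 4557 genes, 1765 higher and 2792 lower, a higher share of 38.7% that became 49.0% with median-ratio scaling, which moved the median of all genes by 0.11. The largest positive terms under the fixed rule were Tmem233 (5.41), D0H4S114 (4.42), Col1a1 (4.16), Gdap1 (4.05) and Ky (3.98) and the largest negative ones Mt1 (-6.72), Mt2 (-6.48), Ryr3 (-5.79), Lcn2 (-5.49) and Trim63 (-4.52). Of the genes fixed beforehand, Fbxo32 (-3.50), Il6ra (-4.20), Foxo1 (-3.18), Cdkn1a (-3.63) and Socs3 (-1.59 ± 0.43) had negative terms. The call for Socs3 was lost without both libraries that share a header (-1.37). All 30 proteasome subunits had negative terms (0 and 30 adjusted over the list alone). So did 22 of 27 autophagy genes (1 and 22 adjusted over the list alone), or 14 under quantile scaling, 19 of 27 FoxO and glucocorticoid genes (4 and 19 adjusted over the list alone) and 17 of 20 ribosome biogenesis genes (0 and 19 adjusted over the list alone). Positive terms were called for 18 of 33 matrix genes (19 and 3 adjusted over the list alone) and 6 of 7 tendon markers (7 and 0 adjusted over the list alone). Camera with an estimated correlation called 0 of 33 lists, 5 at an unadjusted p under 0.05, against 14 with the preset correlation and 20 by fry. Camera at the estimated correlation gave an adjusted p of 0.247 for the proteasome, autophagy, ribosome biogenesis, the matrix and tendon, and 0.251 for the FoxO list. The count of called genes was 2595 without both libraries that share a header.

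**Figure D5:**
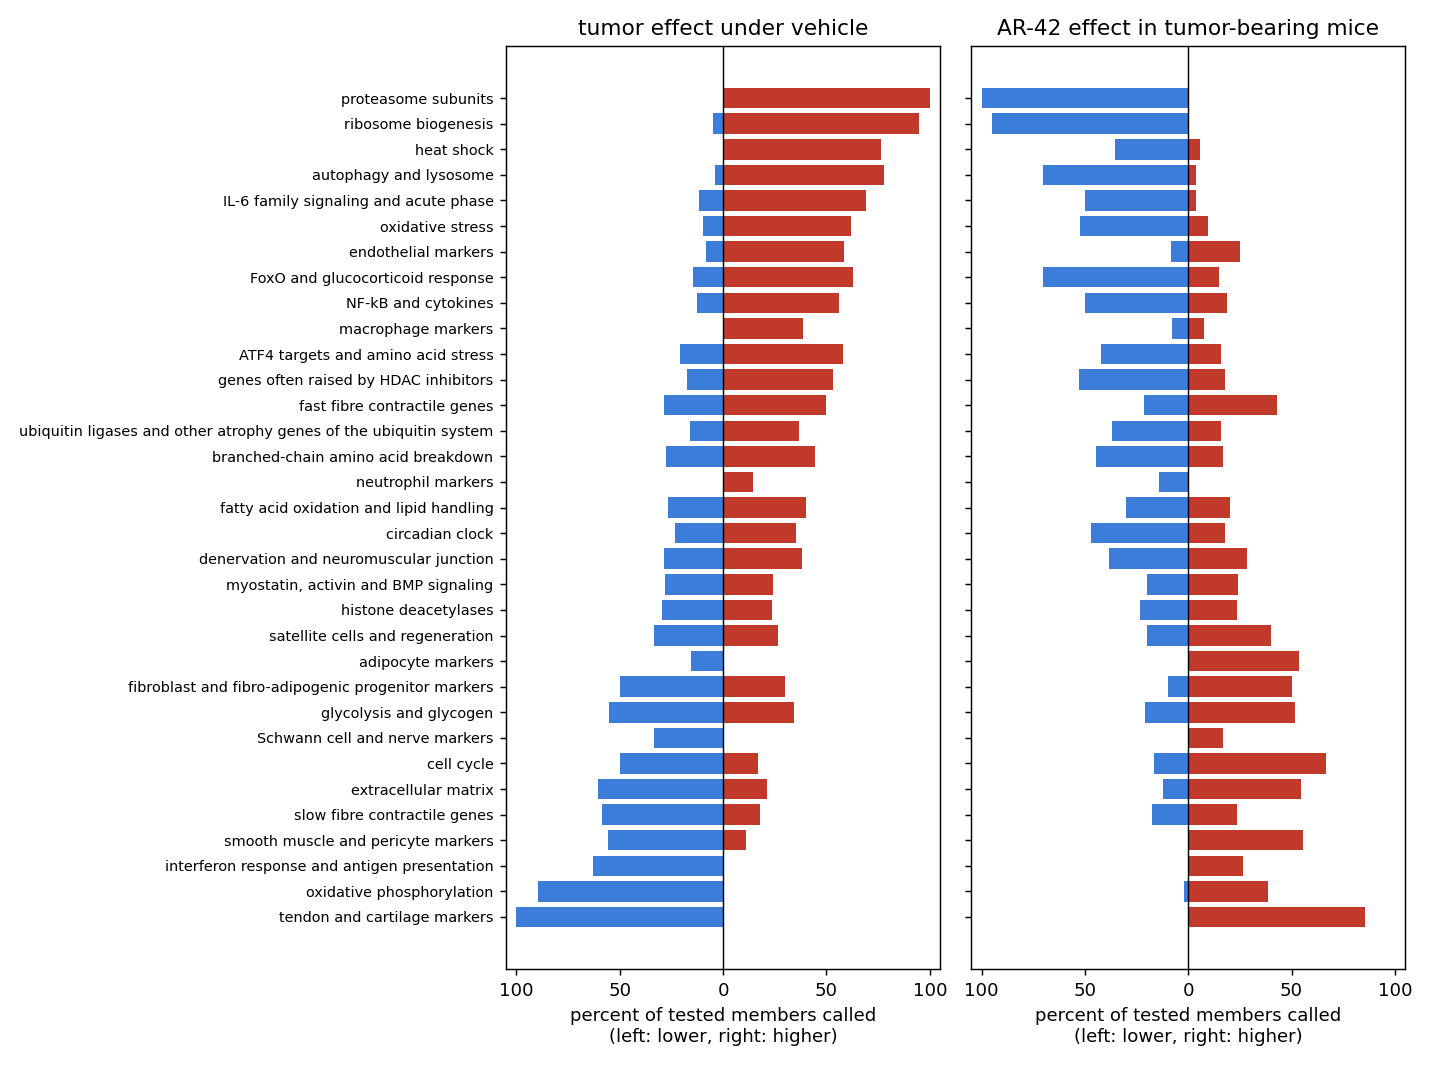
Percent of the tested members of 33 gene lists called lower (bars to the left) and higher (bars to the right) in the tumor effect under vehicle and the AR-42 effect in tumor-bearing mice, genes listed at 0 included. All 30 proteasome subunits are higher with the tumor and lower with AR-42.

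The comparisons that share tumor-free vehicle libraries were set against chance. The tumor effect under vehicle and the AR-42 effect in tumor-free mice correlated across genes at r = 0.243, against 0.503 in simulations of unchanged groups, with a covariance of 0.111 against 0.0395. They shared 184 higher genes, where independent lists would share 142, and 168 lower genes, where these would share 66.5. Fkbp5, Mt1, Mt2 and Cdkn1a are among the former and Col1a1, Col1a2 and Tnmd among the latter. Genes higher with the tumor and lower with AR-42 numbered 22 against 85.3. Those lower with the tumor and higher with AR-42 numbered 113 against 111, near the number for independent lists. The AR-42 effect in tumor-free mice and the comparison of AR-42-treated tumor-bearing with vehicle-treated tumor-free muscle shared 179 higher genes against 31.2 and 174 lower against 23.7, with r = 0.471 against a simulated 0.502 and a covariance of 0.124 against 0.0393. The tumor effect under vehicle and the latter comparison shared 477 higher genes against 269 and 690 lower against 265, with r = 0.517 against 0.503 and a covariance of 0.302 against 0.0394. Without genes listed at 0, the covariances of these pairs were smaller, at 0.0715, 0.0836 and 0.191 in the order given, with r = 0.219, 0.527 and 0.479. In these pairs r lay below or near its value for unchanged groups, so r alone shows no relation beyond the shared libraries. Part of each excess may come from the shared controls.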

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

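The tests weighed here on clock and hemoglobin genes and on genes listed at 0 were chosen after the results were seen. The counts of other splits of the samples were planned.

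The interaction passed limma's test for 4557 genes. For these the AR-42 effect differed with and without a tumor and, equally, the tumor effect with and without AR-42. Largest among the measurable named genes were positive terms for Tmem233 (5.41), D0H4S114 (4.42), Col1a1 (4.16), Gdap1 (4.05) and Ky (3.98) and negative terms for Mt1 (-6.72), Mt2 (-6.48), Ryr3 (-5.79), Lcn2 (-5.49) and Trim63 (-4.52), all log2 values. Over 100 splits of the 12 libraries into 4 groups of 3, 1 split, the real one, gave as many genes, and the highest other gave 4009. Splits that parted the tumor-bearing vehicle libraries gave at most 6, since they put the distance of these libraries from the rest into the spread. With 4 other splits that kept them together, the splits that can compete are too few for a share under 0.05, and the count rests largely on those 3 libraries. The 10 splits of 6 libraries are too few for a share under 0.05. Each of them other than the real one mixes both groups and puts any difference between them into the spread. Its count would be low with or without a real difference, so the counts below lend no support. The real split gave 6810 genes against at most 1 in the tumor effect under vehicle, 6240 against 1 for AR-42 in tumor-bearing mice, 711 against 3 for AR-42 in tumor-free mice, 1906 against 3 for AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle, and 1061 against 6 for the tumor effect under AR-42. For the recovery, 1 of 100 splits of 9 libraries, the real one, gave as many as 4938 genes moved back, and the highest other 4692, among 5 splits that kept the tumor-bearing vehicle libraries together. Splits that parted them gave at most 274, so here too the splits that can compete are too few.

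Loci without a gene symbol stood outside the comparisons, and 401 of 3182 tested were higher in tumor-bearing than in tumor-free vehicle muscle, with 662 lower.

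Abundant genes, many of them muscle genes, are listed at 0 in whole groups. At 0 in at least 1 whole group and at 100 FPKM or more in all 3 libraries of another are 14 loci with a symbol, Snord69, Snord91a and Olfr56 among them. Of 231 loci, with or without a symbol, that reach 100 FPKM and are at 0 in any library, 21 are at 0 in whole groups only. Absence of the transcripts is argued against by 8 of 17 sarcomere, energy and housekeeping genes at 0 in all 3 tumor-free vehicle libraries, Acta1, Ckm and Gapdh among them, which such muscle needs. Loss of a value in the quantification at loci with the most fragments may account for it: the highest FPKM times exon length of its 12 protein-coding loci had a median percentile of 94.8 among 1527 other protein-coding loci that reach 100 FPKM, with a lowest of 82.7 (Pdk4). The other loci needed 100 FPKM in any library only, a looser condition. Nor can the test say why a locus has a value in 1 group and none in another. Ubc and Rif1, at 0 in 3 groups and far below 100 FPKM in the other, are not covered by this test, and Rif1, whose end lies 14263 bases from that of Neb, is above 0 in the same 3 libraries as Neb. The Cufflinks settings are not given in the sources used here, and the direction of these genes stays open.

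Hemoglobin genes were low in tumor-free AR-42 and high in tumor-bearing AR-42 muscle. The scaling of the values is argued against as the whole source: the smallest log2 fold change of 3 globin genes in the tumor effect under AR-42 was 3.42 across both other scalings. Different amounts of blood in the muscle pieces may account for the pattern, since the ratio of Beta-s to Hba-a2 varied 1.86 times between the highest and lowest of the 12 libraries while Beta-s itself varied 25.4 times. A change in the blood itself with tumor or drug stays open and was not tested. Of 8 red blood cell markers fixed beforehand 4 were tested.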

How the results depend on the processing

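Of the alternatives, those without genes listed at 0, with the largest locus only, without both columns that share a header, and without a block on 9 libraries were chosen after seeing the data. Of 112 pairs of a named gene and a comparison, all 112 kept their direction in every alternative run and 80 also their call. Most of these genes were named for large changes that part the libraries of the groups compared. The alternatives use the same libraries, so a kept direction was largely fixed by that choice. Of 2370 gene values, 2227 stayed on their side of the threshold, 143 fell short and 0 reversed. Of 8052 counts of list members, 6788 stayed within 1.5 times and 1264 moved. Without alternatives, limma called 6810 genes in the tumor effect under vehicle, 6240 for AR-42 in tumor-bearing mice, 711 for AR-42 in tumor-free mice and 1906 for AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle. It called 1061 in the tumor effect under AR-42 and 4557 in the interaction, and 4938 of the 6810 moved back in the recovery. With an absolute log2 fold change of at least 1 in addition, which is stricter by construction, 2509 genes were called in the tumor effect under vehicle, 2031 for AR-42 in tumor-bearing mice, 145 for AR-42 in tumor-free mice, 326 for AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle, 183 in the tumor effect under AR-42, 2178 in the interaction and 1537 in the recovery. With a mean of at least 5 FPKM, which tests 8238 genes, 424 were called for AR-42 in tumor-free mice and 1244 for AR-42-treated tumor-bearing against tumor-free vehicle muscle. Library weights gave 2603 for AR-42 in tumor-free mice, 4722 for AR-42-treated tumor-bearing against tumor-free vehicle muscle and 3296 for the tumor effect under AR-42, and the cause was not tested. Fitting the compared groups alone, which leaves fewer samples, gave 1260 and 577 for the latter 2. Quantile scaling gave 687 for the tumor effect under AR-42, and the cause was not tested. Without both columns that share a header, which leaves 1 tumor-free AR-42 library assumed to vary like the others, 33 genes were called for AR-42 in tumor-free mice, 67 in the tumor effect under AR-42 and 2595 in the interaction. Leaving out each library in turn, which leaves fewer samples, gave 5855 to 6695 genes for the tumor effect under vehicle, 5350 to 6229 for AR-42 in tumor-bearing mice and 211 to 471 for AR-42 in tumor-free mice. It gave 907 to 1633 for AR-42-treated tumor-bearing against tumor-free vehicle muscle, 160 to 747 for the tumor effect under AR-42, 3832 to 4813 for the interaction and 4108 to 5041 for the recovery. In the list tests, camera with an estimated correlation called 0 lists in each comparison, while the preset correlation called 13, 14, 8, 8, 14 and 14, and fry 22, 21, 10, 12, 10 and 20, in the order in which the report gives the comparisons. The preset camera assumes a correlation, and fry compares a list with no other genes. Same-numbered libraries correlated at -0.0283 to 0.133, over 0.1 in 2 of 9 pairs, so the numbers were not taken to pair them. With the replicate block on 9 libraries, 6579 genes were called for the tumor effect under vehicle and 6089 for AR-42 in tumor-bearing mice, against 6445 and 5903 without it on the same libraries. AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle gave 1367 against 1404 and the recovery 4778 against 4628. With the block, Myog had an adjusted p = 0.0522 for AR-42 in tumor-bearing mice and 0.0680 for AR-42-treated tumor-bearing against vehicle-treated tumor-free muscle, at folds that did not change. No paired analysis was possible because 2 tumor-free AR-42 columns carry no number, for the AR-42 effect in tumor-free mice, the tumor effect under AR-42 and the interaction. Quantile and median-ratio scaling kept 5985 and 6343 of the calls of the tumor effect under vehicle in their direction, 5014 and 5648 for AR-42 in tumor-bearing mice, and 642 and 703 for AR-42 in tumor-free mice. In the interaction, 1765 higher and 2792 lower genes became 2265 and 2354 with median-ratio scaling. The depth of the libraries is unknown, so what it limits cannot be stated.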

Other observations

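The genes and tests of this part were chosen after the values were seen, though the clock genes are a list fixed beforehand.

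Genes of the circadian clock differed between the groups. In tumor-free vehicle, tumor-free AR-42, tumor-bearing vehicle and tumor-bearing AR-42 muscle, in that order, Arntl, which encodes the activator BMAL1, stood at 1.93 ± 0.308, 7.03 ± 1.07, 28.2 ± 2.00 and 23.3 ± 7.32 FPKM (n = 3 per group), and Clock, its partner, at 3.60 ± 0.599, 3.47 ± 0.335, 9.36 ± 0.446 and 8.55 ± 2.76 FPKM. Dbp, an output gene driven by that pair, stood at 64.0 ± 5.85, 39.0 ± 15.5, 2.50 ± 1.02 and 6.13 ± 5.61 FPKM, and Bhlhe41, a repressor, at 31.3 ± 2.71, 22.1 ± 8.88, 4.34 ± 1.36 and 7.05 ± 1.55 FPKM. Cry2, a repressor, stood at 15.7 ± 1.79, 16.5 ± 1.52, 63.0 ± 14.1 and 12.8 ± 0.145 FPKM, and Rora, an activator of Arntl, at 20.1 ± 1.50, 25.8 ± 4.11, 86.0 ± 20.2 and 21.9 ± 2.29 FPKM. Of 17 clock genes tested, 10 were called in the tumor effect under vehicle by limma, where 56.9% of all tested genes were called, so the number alone does not set the clock genes apart. Nr1d1, the repressor REV-ERB alpha, was lower with AR-42 both in tumor-free (-0.68 ± 0.12) and in tumor-bearing mice (-0.76 ± 0.12, log2 fold change ± standard error). In AR-42-treated tumor-bearing mice Cry2 and Rora were near their levels in tumor-free muscle, while replicate 1 stood apart from replicates 2 and 3 for other clock genes: 14.8 against 27.1 and 27.8 FPKM for Arntl, 12.6 against 3.62 and 2.21 for Dbp, 31.1 against 13.7 and 4.39 for Per1 and 13.9 against 5.71 and 3.32 for Per3.

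The scaling of the values is argued against as the source, since 9 of the 10 called clock genes kept call and direction under both other scalings. A different hour of harvest between the groups may account for part of these changes, and with 10 clock genes called and no hour given in the labels it cannot be told apart from an effect of the tumor or the drug on the clock, because the hour and the group may go together. The biological difference between tumor-bearing and tumor-free mice stays open and was not tested apart from it.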
